A study of Rattus norvegicus with 4 samples.

How the data were processed

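The samples were cultures of neonatal rat ventricular cardiomyocytes infected with adenovirus for beta-galactosidase (2 samples) or Smyd2 (2 samples), and groups and replicate numbers were taken from the sample titles. The titles of all 4 samples start with siScr, which the labels do not explain, and the treatment protocol also mentions small interfering RNA. Whether all 4 cultures also received such an RNA is not settled here. Per the labels' protocols, total RNA was extracted with a column kit, amplified with Agilent's low-input kit and labelled with Cy3, which makes these single-colour arrays. Per the submitters' processing notes, limma was used, with no version or step named. Background correction, the normalization method and the handling of replicate spots are not given in the sources used here.

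The deposited table holds log2 intensity values, 1 row for each of 62976 features per array. The log2 unit and the normalization by the authors were read from the values. The 4 columns run from 2.07 to 16.00 with a median of 4.70 each and quartiles of 3.25 and 9.74, as quantile normalization would leave them. Features are not centred. Such normalization removes any difference between arrays in overall signal, so the differences reported are relative to the bulk of the features. The median difference over all genes was 0.011. The table carries no flags for detection or saturation, so a dim gene could not be marked as absent. Each array held 205 features above 15.9, which was taken as the top of the scale. A gene there on both control arrays and lower on the other arrays has only a lower bound for its difference, and for a gene there in both groups no difference can be read.

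Features were named through the platform's annotation, which can be old. Of the features, 36191 had 1 gene symbol, 0 had several and 26785 were not named. Accessions of 28236 named features matched the RefSeq gene table of the rat reference assembly, and 457 further features were named through an older symbol that belongs to 1 current gene, so that 3339 symbols were updated. For each of 19868 genes the feature with the highest mean over the 4 arrays was used; 6524 genes had several features, and where the features of a named gene disagreed in direction this is stated. No filter on dim genes was applied. No probe positions were used, and no coordinates are reported.

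Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend, on the log2 values as deposited, 2 groups, no block), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and a prior of 3.01. An exact permutation test of a single gene cannot go below p = 0.333 with 2 arrays against 2. Gene lists, 30 in number, were tested with camera at a preset correlation of 0.01, adjusted over the lists, for lists with at least 5 measured members. Beside this, members were tested adjusted over the list alone, lists were tested with camera using an estimated correlation and with fry, and medians were taken over all measured members. The lists were the SMYD family; sarcomere and Z-disc; fetal and hypertrophic stress programme; calcium handling and ion channels; adrenergic and natriuretic signalling; oxidative phosphorylation; fatty acid oxidation; glycolysis; heat shock proteins and chaperones; unfolded protein response; p53 targets; apoptosis; cell cycle; interferon; inflammatory cytokines. They went on with TGF-beta targets, immediate early genes, NRF2, atrophy and autophagy, cholesterol and lipid synthesis, histone methyltransferases and demethylases, cardiac transcription factors, ribosomal proteins, and markers of fibroblasts, endothelium, smooth muscle and pericytes, leukocytes, epicardium, Schwann cells and erythroid cells. A listed gene that is missing from the counts was not analysed here.

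The groups, tests, lists and alternatives were set before the data were examined, except where stated. So was the rule for named genes. It takes the SMYD family, the 10 higher and 10 lower genes with the largest change past the threshold whose groups do not overlap, and 2 to 4 members of each list with the largest statistic. Where fewer genes pass, those with the smallest unadjusted p fill the place and are named as not past the threshold, leaving out symbols that are only locus names. As no gene passed, all 20 were chosen in that way.

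The fits were tested on simulated data, in 20 runs with 200 changed genes drawn from the real means and the fitted spread, of which unchanged genes had an unadjusted p under 0.05 in 5.05% of cases. Camera was tested on 50 runs of simulated lists for each setting. Alternatives were repeated quantile normalization, centring on the median, leaving out dim genes, an intensity trend with a robust prior, the replicate number as a block, the mean of all features, every feature on its own, a size threshold of 1 log2 unit, and leaving out each array in turn, where the lone array of a group is assumed to vary like the other group.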

Results

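Gene expression was measured in ventricular cardiomyocytes, the contractile cells of the heart's pumping chambers, taken from Sprague-Dawley rats on postnatal day 3. After 48 h of culture in 5% horse serum with 20 µM cytosine arabinoside, which holds back dividing cells, adenovirus was applied for 48 h to express either Smyd2 or, as the control, the bacterial reporter beta-galactosidase. Each of the 2 groups held 2 samples, which the series design calls biological replicates, and each sample was hybridised to its own single-colour array. All 4 titles start with siScr, and the labels do not settle whether every culture also received a small interfering RNA. The deposited log2 intensities covered 62976 features per array and had a median of 4.70 on each of the 4 arrays. They were reduced to 19868 named genes with 1 feature each. With 2 arrays per group, the number of arrays limited the precision throughout. The 2 control arrays had a median absolute log2 difference of 0.3753 from each other. Control replicate 1 differed about as much from the arrays labelled Smyd2 (0.3764 and 0.3735), and control replicate 2 slightly more (0.3887 and 0.3853). The 2 arrays labelled Smyd2 were closer to each other, at 0.2548. A fit that leaves out a control array takes its residual spread from that closer pair alone. Values below are mean log2 intensities ± SD over the 2 arrays of a group, and differences are the arrays labelled Smyd2 minus the control arrays.

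The comparison asked what excess SMYD2, a lysine methyltransferase of the SET and MYND domain family, does to the transcripts of cardiomyocytes. The single feature that names Smyd2 was not higher on the arrays labelled Smyd2. It read 8.72 and 8.86 on the control arrays and 8.92 and 8.42 on the arrays labelled Smyd2, so the groups overlapped. The log2 difference was −0.12 (SE 0.28, 95% interval −0.83 to 0.60, limma adjusted p = 0.913). Leaving out Smyd2 replicate 2 turned the difference to 0.13. The position of this probe on the transcript is not in the tables used here, and a probe outside the expressed construct checks nothing about the labels. The groups are therefore called by their labels, and every direction below rests on those labels.

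Among the relatives of Smyd2, Smyd1, the member specific to heart and skeletal muscle, and Smyd4 fell by limma's test adjusted over the list alone. Smyd1 read 7.91 ± 0.82 on the control arrays and 5.55 ± 0.45 on the arrays labelled Smyd2, a 5.14-fold lower level. Its difference of −2.36 was near the sarcomere and Z-disc list's median of −2.15. A response of Smyd1 apart from the general fall of muscle genes therefore cannot be read. Smyd4 read 5.27 ± 0.22 and 4.19 ± 0.05, the latter dim, so the size of its fall may be a lower bound. Smyd3 and Smyd5 differed by 0.64 (SE 0.31) and 0.38 (SE 0.33) log2 units and did not pass. As a list, 2 of the 5 members were higher and 3 lower, with a median of −0.12 and a camera adjusted p of 0.336. Over all genes tested, neither Smyd1 (adjusted p = 0.222) nor Smyd4 (adjusted p = 0.250) passed.

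The 10 higher and 10 lower genes with the smallest p included the vessel growth factors Angpt2 and Vegfd on the higher side, and Tnni1 and Nppb of the fetal and stress programme on the lower side. Car3, the cytosolic carbonic anhydrase of muscle and fat, read 6.25 ± 0.22 on the control arrays and 10.25 ± 0.41 on the arrays labelled Smyd2, and its other feature differed by 1.49. Vegfd, a lymphatic growth factor, differed by 3.39 log2 units (SE 0.34). Angpt2, a vessel-remodelling ligand, read 3.20 ± 0.39 and 6.65 ± 0.41. Its control level was dim, with no flag to show whether it lay above background, so its difference is given as at least 3.45. The hyaluronidase Cemip, the endothelial lectin Cd93 and the collagen receptor Itga11 differed by 2.52, 2.68 and 2.39. C1qtnf1, Akr1c19 and Smoc1 differed by 2.72, 2.25 and 2.14, and the potassium channel subunit Kcnv2, the last of the 10, read 5.59 ± 0.44 and 8.08 ± 0.01. The control means of C1qtnf1 (4.30) and Akr1c19 (4.03) were dim too, so their differences may be lower bounds. On the lower side, Tnni1, the slow skeletal troponin I that the fetal heart uses, read 13.41 ± 0.03 and 10.98 ± 0.09. Epn3, Inpp5j and Thnsl1 differed by −2.54, −2.39 and −2.43 log2 units. F2rl1 read 5.48 ± 0.01 and 3.04 ± 0.08, the latter dim as well, so its 5.42-fold lower level is given as a lower bound. Mgat4a, Cidea, Gnao1 and Fn3k differed by −2.43, −2.41, −2.18 and −2.25. The other feature of Epn3 differed by −0.99, and the 14 features of Gnao1 ranged from −2.48 to −0.12. Nppb, the precursor of brain natriuretic peptide, read 15.99 on both control arrays, at the top of the scale, against 13.83 ± 0.08, so its 4.48-fold lower level is a lower bound.

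None of these 20 genes passed the threshold, since each had a limma adjusted p of 0.154. In all 20 the groups did not overlap. So did 42.7% of all genes, where chance gives 33.33% with 2 arrays against 2. With limma, 0 genes had an adjusted p under 0.05, and 2363 had an unadjusted p under 0.05, of which 1094 were higher and 1269 lower. The variance model decided this count: with an intensity trend and a robust prior 383 genes passed, 95 higher and 288 lower, and all 20 genes named above were among them. An intensity trend alone, added after the data were seen, gave 243 genes, 47 higher and 196 lower. The count at an unadjusted p under 0.05 was 1149 without Smyd2 replicate 1, 1266 without Smyd2 replicate 2, 3151 without beta-galactosidase replicate 1 and 2825 without beta-galactosidase replicate 2. Limma's adjusted test was also run on simulated data for this comparison, in which 200 of 19868 genes were changed. It called 0.2% of genes changed by 1 log2 unit, 5.8% at 2, 63.6% at 3 and 83.7% at 4. These percentages depend on the share of changed genes, and no other share was simulated. Unchanged genes had an unadjusted p under 0.05 by limma in 5.05% of simulated cases. As a share of 19868 genes, the unadjusted counts without either Smyd2 array lay only slightly above this.

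Genes of the contractile apparatus were lower as a group on the arrays labelled Smyd2. Of the 26 measured members of the sarcomere and Z-disc list, 24 were lower and 2 higher, with a median log2 difference of −2.15, or 4.45-fold. None passed over all genes, and 21 fell when adjusted over the list alone. Cardiac troponin I, Tnni3, read 14.83 ± 0.05 on the control arrays and 12.66 ± 0.10 on the arrays labelled Smyd2. The ventricular light chain Myl3 read 15.72 ± 0.15 and 13.50 ± 0.22. Csrp3, a Z-disc protein, and Lmod2, which sets thin filament length, differed by −2.35 (SE 0.25) and −2.44 (SE 0.26). The list fell by camera with its preset correlation of 0.01 (adjusted p = 2.27e-23), while the correlation estimated among its members was 0.36. With simulated members correlated at 0.3 the preset called 33.4% and 33.87% of unchanged lists. No higher correlation was simulated, so the share of false calls above 0.3 is unknown. Over the lists the estimate ranged from −0.067 (Schwann) to 0.96 (cholesterol). It was 0.56 for oxidative phosphorylation, 0.65 for calcium handling, 0.77 for fatty acid oxidation and 0.45 for interferon. Camera with the estimated correlation had an adjusted p = 0.668, but in simulation it called 0% of shifted lists. Its values, here and for the lists below, therefore count neither for nor against a shift. The control arrays were at the top of the scale for 3 further members, whose differences are lower bounds, and both groups were there for 1.

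**Figure D1:**
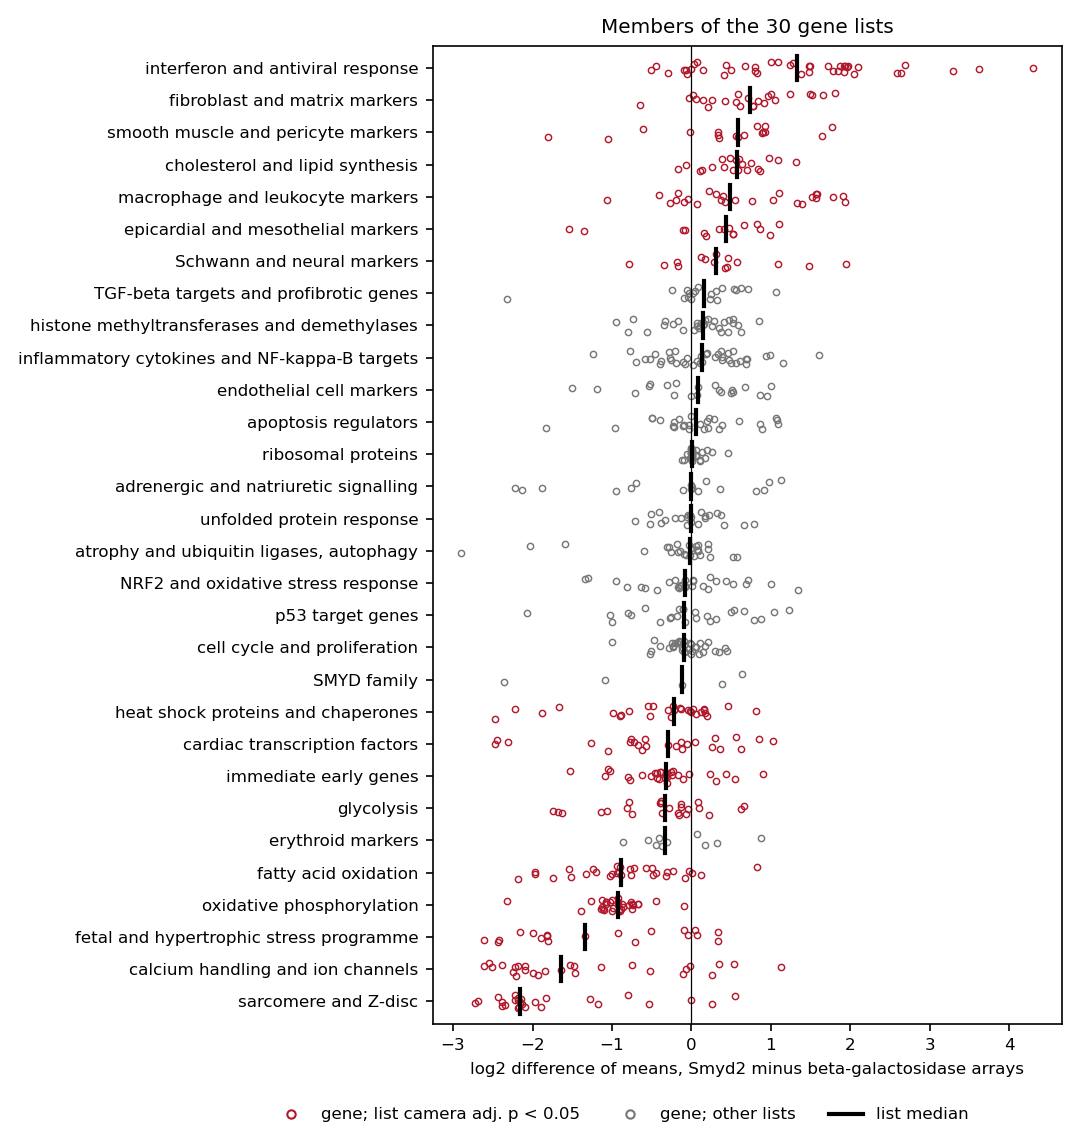
Log2 difference between the mean of the 2 Smyd2 arrays and the mean of the 2 beta-galactosidase arrays, for every measured member (circles) of the 30 gene lists, ordered by list median (black bars); red marks lists with a camera adjusted p under 0.05 at the preset correlation. The sarcomere list lies lowest, with a median of −2.15, and the interferon list highest, with 1.33.

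The genes that move calcium and carry cardiac currents were lower too. In that list 23 of 27 members were lower and 4 higher, with a median of −1.64, and 16 fell when adjusted over the list alone. Phospholamban (Pln), the brake on the sarcoplasmic calcium pump, read 13.60 ± 0.49 on the control arrays and 11.21 ± 0.16 on the arrays labelled Smyd2. The ryanodine receptor Ryr2 differed by −2.61 (SE 0.41), the calcium store protein Casq2 by −2.21 (SE 0.35) and the sodium pump regulator Fxyd1 by −2.09 (SE 0.27). Of the fetal and hypertrophic stress programme, 15 of 19 members were lower and 4 higher, with a median of −1.34, and 9 fell when adjusted over the list alone. Atrial natriuretic peptide, Nppa, read 15.77 ± 0.11 and 13.95 ± 0.10, and skeletal actin, Acta1, 13.01 ± 0.31 and 10.39 ± 0.29. Both lists fell by camera (adjusted p = 3.98e-10 for calcium handling and 1.22e-08 for the stress programme), with an adjusted p = 0.668 for each with an estimated correlation. Without beta-galactosidase replicate 2 the calcium handling median was −0.96.

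Of 25 cardiac transcription factors, 17 were lower and 8 higher, with a median of −0.29, and 3 fell when adjusted over the list alone. Those 3 were Nkx2-5, the homeobox factor of the heart (9.05 ± 0.59 and 6.58 ± 0.03), Irx4, a ventricular homeobox factor (−2.45, SE 0.33), and the nuclear receptor Esrrg (−2.31, SE 0.25). The other feature of Esrrg went the opposite way, by 0.56. Camera called the list lower (adjusted p = 0.00611), with an adjusted p = 0.668 with an estimated correlation. Without beta-galactosidase replicate 2 its median was −0.31 and its camera adjusted p was 0.0569. Markers of some other cell types moved beside these muscle lists, with a median of 0.74 for fibroblast markers and 0.49 for leukocyte markers, while those of endothelium (0.087) and erythroid cells (−0.34) were not called.

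Transcripts of mitochondrial energy metabolism were lower on the arrays labelled Smyd2. All 32 measured members of the oxidative phosphorylation list were lower, with a median of −0.93, or 1.90-fold, and 27 fell when adjusted over the list alone. Cox8b, the muscle form of a cytochrome oxidase subunit, read 13.24 ± 0.77 on the control arrays and 10.93 ± 0.08 on the arrays labelled Smyd2. Cyc1 and the electron carrier Cycs differed by −1.26 (SE 0.24) and −1.39 (SE 0.29). In the fatty acid oxidation list 28 of 31 members were lower and 3 higher, with a median of −0.89, and 5 fell when adjusted over the list alone. The coactivator of mitochondrial genes Ppargc1a read 5.78 ± 0.08 and 3.60 ± 0.13, with −0.34 for its other feature. The latter level of Ppargc1a was dim, so the size of its fall may be a lower bound. The fatty acid carrier Fabp3 read 13.56 ± 0.28 and 11.59 ± 0.11. Of 24 glycolysis genes, 19 were lower and 5 higher, with a median of −0.33, and 5 fell when adjusted over the list alone. Among them were the heart form of lactate dehydrogenase, Ldhb (−1.68, SE 0.24), the lactate transporter Slc16a1 (−1.64, SE 0.27) and the muscle mutase Pgam2 (−1.74, SE 0.38).

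The 3 metabolic lists fell by camera, with adjusted p = 1.45e-19 for oxidative phosphorylation, 1.72e-08 for fatty acid oxidation and 0.000765 for glycolysis. With an estimated correlation the adjusted p values were 0.668, 0.70 and 0.668. The fatty acid oxidation median was −0.37 without beta-galactosidase replicate 2. Fibroblast markers moved beside these lists with a median of 0.74.

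Interferon-responsive genes were higher on the arrays labelled Smyd2, although both groups had received adenovirus. Of 42 measured members 35 were higher and 7 lower, with a median of 1.33, or 2.52-fold, and 18 rose when adjusted over the list alone. Bst2, the antiviral factor tetherin, read 7.39 and 5.78 on the control arrays and 11.85 and 9.92 on the arrays labelled Smyd2. The immunoproteasome subunit Psmb8 read 9.66 ± 0.51 and 11.76 ± 0.44. Ifih1, a sensor of double-stranded RNA, and Ifi44 differed by 1.49 (SE 0.25) and 2.04 (SE 0.41). Camera called the list higher (adjusted p = 7.31e-12), with an adjusted p = 0.668 with an estimated correlation. The median was 0.86 without Smyd2 replicate 1 and 1.75 without Smyd2 replicate 2. Leukocyte markers were higher beside this list, in 19 of 26 members with a median of 0.49, and in all 9 of those with a mean of 6 or more, with a median of 1.57.

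Inflammatory cytokines and targets of NF-kappa-B did not pass, with 25 of 41 members higher, 16 lower, a median of 0.14 and a camera adjusted p of 0.336. None of them passed adjusted over the list alone. Without beta-galactosidase replicate 1 the list was called higher, at a median of 0.33, and without beta-galactosidase replicate 2 its median turned to −0.12. Its members with the largest statistic were the pattern receptor Ptx3 (0.93, SE 0.26), the chemokines Ccl5 (1.15, SE 0.35) and Cxcl2 (−1.24, SE 0.42), and Bcl3 (0.98, SE 0.31). Cxcl2 was dim on the arrays labelled Smyd2 (3.97 and 4.02), so the size of its fall may be a lower bound.

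**Figure D2:**
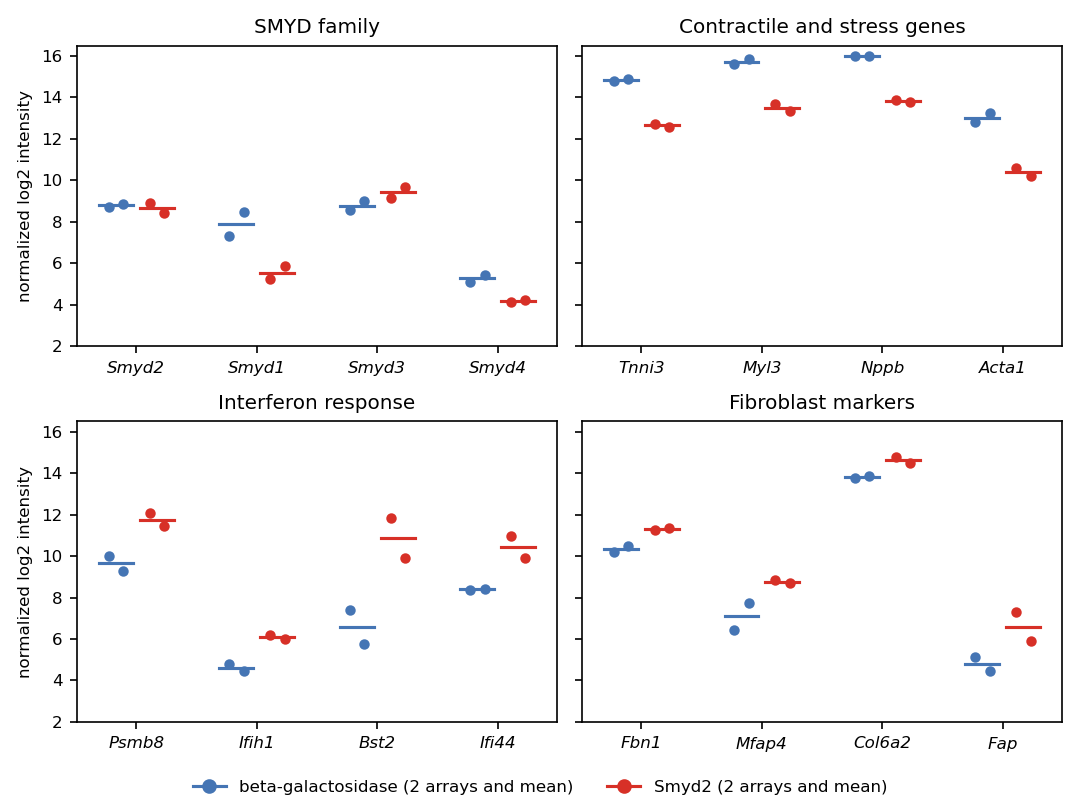
Normalized log2 intensity of 16 genes on each of the 4 arrays, 2 of beta-galactosidase (blue) and 2 of Smyd2 (red), with group means as bars. The Smyd2 feature overlaps between groups (control mean 8.79, Smyd2 mean 8.67), while Tnni3, Myl3, Nppb and Acta1 are lower and the interferon and fibroblast genes shown are higher on both Smyd2 arrays; no gene passed over all genes tested.

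Among markers of other cells that heart cultures can hold, those of fibroblasts and matrix were higher in 22 of 24 members, with a median of 0.74, and none passed adjusted over the list alone. The microfibril gene Fbn1 read 10.34 ± 0.22 on the control arrays and 11.31 ± 0.06 on the arrays labelled Smyd2, and Mfap4 and Col6a2 differed by 1.65 (SE 0.47) and 0.84 (SE 0.24). Macrophage and leukocyte markers were higher in 19 of 26 members, with a median of 0.49, and none passed adjusted over the list alone. The pan-leukocyte gene Ptprc was dim on the control arrays (3.52 ± 0.01, against 5.42 ± 0.65), so its difference is given as at least 1.90. The lysozyme gene Lyz2 differed by 1.78 (SE 0.59). Lyve1, a marker of lymphatic vessels and resident macrophages, was dim in both groups (3.98 ± 0.26 and 2.92 ± 0.67). Both lists rose by camera, with adjusted p = 1.73e-05 for fibroblasts and 0.00635 for leukocytes, and with an estimated correlation the adjusted p values were 0.668 and 0.741.

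The fibroblast median was 0.33 without beta-galactosidase replicate 1. The leukocyte median was 0.15 and no longer called without Smyd2 replicate 1, 0.39 and not called without beta-galactosidase replicate 2, and 1.00 without Smyd2 replicate 2, and it was 0.77 without beta-galactosidase replicate 1. Endothelial markers showed no shift as a list, with 12 of 21 members higher, 9 lower, a median of 0.087 and a camera adjusted p of 0.858. None of them passed adjusted over the list alone; Eng differed by 0.95 (SE 0.31) and the water channel Aqp1 by −1.19 (SE 0.45).

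Smooth muscle and pericyte markers were higher in 13 of 17 members, with a median of 0.59. Adjusted over the list alone 3 rose, among them the mural cell genes Notch3 (1.64, SE 0.28) and Rgs5 (1.77, SE 0.34). The 2 that fell were desmin, Des (−1.81, SE 0.26), the intermediate filament that cardiomyocytes also carry, and the potassium channel subunit Abcc9 (−1.05, SE 0.24). Schwann and neural markers were higher in 11 of 15 members, with a median of 0.31; 1, the tubulin gene Tubb3, rose adjusted over the list alone (7.29 ± 0.12 and 9.23 ± 0.26). Epicardial and mesothelial markers were higher in 12 of 16 members, with a median of 0.44, and none passed adjusted over the list alone; Tbx18 differed by 0.66 (SE 0.25) and Msln by 0.82 (SE 0.32). These 3 lists passed camera narrowly, with adjusted p = 0.0474, 0.0195 and 0.0445, and with an estimated correlation the adjusted p values were 0.727, 0.668 and 0.70.

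The smooth muscle median was 0.03 without beta-galactosidase replicate 1 and 0.50 without Smyd2 replicate 1, and the list was called in neither case. The Schwann list was not called without beta-galactosidase replicate 1 (median 0.37) or without Smyd2 replicate 2 (median 0.30), and its median was 0.47 without Smyd2 replicate 1. The epicardial median was 0.21 without beta-galactosidase replicate 2, 0.41 without Smyd2 replicate 2 and 0.79 without beta-galactosidase replicate 1; only the last of these kept the call. The epicardial call also ended with the replicate number as a block, at a camera adjusted p of 0.0584. Erythroid markers did not pass, with 4 of 10 members higher, 6 lower, a median of −0.34, a camera adjusted p of 0.336 and none past the test adjusted over the list alone. Tfrc, the transferrin receptor, differed by −0.86 (SE 0.23) and Hba-a1 by 0.87 (SE 0.51).

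Of 29 heat shock proteins and chaperones, 20 were lower and 9 higher, with a median of −0.22 and a camera adjusted p of 0.00635, against an adjusted p = 0.668 with an estimated correlation. The 2 that fell adjusted over the list alone were the myosin chaperone Unc45b (12.49 ± 0.66 and 10.27 ± 0.10) and the muscle small heat shock protein Hspb3 (12.54 ± 0.81 and 10.06 ± 0.01). The median was −0.11 without beta-galactosidase replicate 2. Of 30 immediate early genes 25 were lower and 5 higher, with a median of −0.32 and a camera adjusted p of 0.00891, against an adjusted p = 0.70 with an estimated correlation. The phosphatase Dusp5 alone fell adjusted over the list alone (−1.53, SE 0.23), and Nr4a3 differed by −0.80 (SE 0.32). The list was not called without beta-galactosidase replicate 1 (median −0.14) or without Smyd2 replicate 2 (median −0.34).

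Cholesterol and lipid synthesis genes were higher in 18 of 20 members, with a median of 0.58, but the 2 control arrays disagreed about them. Camera called the list higher (adjusted p = 0.00891), with an adjusted p = 0.772 with an estimated correlation, and none passed adjusted over the list alone. The sterol enzyme Nsdhl read 7.48 and 9.04 on the control arrays and 9.61 and 9.55 on the arrays labelled Smyd2, and Lss read 8.90 and 10.20 against 10.58 and 10.47. Without beta-galactosidase replicate 1 the list median turned to −0.31 and was not called, and without beta-galactosidase replicate 2 it was 1.43.

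SMYD2 is known to methylate p53 and histones. As the Smyd2 feature was not higher, lists without a shift here cannot show that SMYD2 leaves these genes unchanged. Of 26 p53 target genes 12 were higher and 14 lower (median −0.094, camera adjusted p = 0.890), and none passed adjusted over the list alone. Pltp differed by 1.22 (SE 0.22) and Gadd45a by −1.03 (SE 0.28). Of 28 apoptosis regulators 15 were higher and 13 lower (median 0.052, 0.0019 without beta-galactosidase replicate 1 and 0.13 without Smyd2 replicate 2, camera adjusted p = 0.403), again with none past the test adjusted over the list alone; Bik differed by −1.83 (SE 0.36) and Bcl2l11, which 1 of its 3 features contradicted, by 1.08 (SE 0.24). Of 31 histone methyltransferases and demethylases 22 were higher and 9 lower (median 0.14, 0.044 without beta-galactosidase replicate 2 and 0.23 without Smyd2 replicate 1, camera adjusted p = 0.327), with none past the test adjusted over the list alone; Ehmt2 differed by 0.85 (SE 0.27) and Kdm4a by 0.62 (SE 0.23). Cell cycle genes, 12 higher and 24 lower of 36, had a median of −0.097 (camera adjusted p = 0.412), and none passed adjusted over the list alone. Their median was −0.25, and the list was called lower, without beta-galactosidase replicate 2, and it was 0.18 without beta-galactosidase replicate 1. Pcna differed by −0.52 (SE 0.24) and cyclin D1, Ccnd1, read 11.02 ± 1.11 and 10.03 ± 0.06.

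Some lists without a shift held members that did pass adjusted over the list alone. Of 17 adrenergic and natriuretic signalling genes 8 were higher and 9 lower (median −0.0016, camera adjusted p = 0.369). The 3 that fell were the alpha-1 adrenergic receptors Adra1a (−2.22, SE 0.30), Adra1d (−2.14, SE 0.40) and Adra1b (−1.89, SE 0.36), and 2 rose, among them the natriuretic peptide receptor Npr2 (0.91, SE 0.23). The 3 features of Adra1a ranged from −2.22 to −0.18, and the feature used was dim on the arrays labelled Smyd2 (4.09 ± 0.44). Of 27 atrophy and autophagy genes 13 were higher and 14 lower (median −0.023, camera adjusted p = 0.336), and 2 fell, the muscle ubiquitin ligases Trim55 (11.00 ± 0.53 and 8.11 ± 0.21) and Trim54 (10.43 ± 0.55 and 8.40 ± 0.01). Of 20 TGF-beta targets and profibrotic genes 13 were higher and 7 lower (median 0.16, 0.073 without beta-galactosidase replicate 1 and 0.24 without beta-galactosidase replicate 2, camera adjusted p = 0.336), and 1 fell, Tgfbi (9.03 ± 0.05 and 6.70 ± 0.51), while Postn differed by 0.71 (SE 0.32).

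In the remaining 3 lists none passed adjusted over the list alone. The unfolded protein response had 10 of 24 members higher and 14 lower (median −0.011, camera adjusted p = 0.885); the chaperone Hspa5 differed by −0.51 (SE 0.27) and Ern1 by −0.70 (SE 0.25). The NRF2 list had 13 of 29 higher and 16 lower (median −0.083, camera adjusted p = 0.984); Gsta1 differed by 1.35 (SE 0.26) and Gstp1 by 0.72 (SE 0.27). Ribosomal proteins had 19 of 30 higher and 11 lower (median 0.0033, camera adjusted p = 0.617), with 15 of the 30 at the top of the scale on all 4 arrays, where no difference could be read; without these the median was 0.063. Rps4x differed by 0.45 (SE 0.23) and Rpl27 by 0.20 (SE 0.25).

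Across the 30 lists, 16 passed camera with its preset correlation of 0.01, 0 passed with an estimated correlation and 0 passed with fry, limma's rotation test of whether a list's genes move 1 way on balance. In simulated lists for this comparison, over 19868 genes, the preset called 0% and 0.13% of unchanged lists without correlation, in the settings with other lists shifted by 1 and by 2 log2 units. Where members shared a correlation of 0.3 it called 33.4% and 33.87% of unchanged lists, and it called 100% of shifted lists in every setting. Correlations above 0.3, which several called lists had by estimate, were not simulated. The estimated correlation called 0% of shifted lists in every setting, with or without correlation, so that test had no power here. Fry was not run on simulated lists, so its power here is unknown. Its smallest adjusted p values were 0.0728 for Schwann and neural markers and 0.0895 for the sarcomere list.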

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

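The comparison below was chosen after the data were seen. Among the 26785 features that the platform annotation does not name, and that no list or gene test by name used, 5 had both arrays labelled Smyd2 at least 2 log2 units above both control arrays. In the opposite direction, 28 unnamed features had both control arrays at least 2 log2 units above both arrays labelled Smyd2. What these features measure was not analysed here, and neither count was set against chance.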

How the results depend on the processing

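The trend or the robust prior taken alone, and the omission of the brightest genes (19748 left), were chosen after the data were seen. The count of 0 genes at an adjusted p under 0.05 became 383 with an intensity trend and a robust prior and 243 with the trend alone, and stayed at 0 with the robust prior alone and under the other alternatives, the replicate block included (0 genes; 2251 at an unadjusted p under 0.05, against 2363). Where the count stayed at 0, the smallest adjusted p ranged from 0.0754 without genes below a mean of 5.42 to 0.590 without Smyd2 replicate 2. The Smyd2 difference ranged from −0.37 to 0.13 over the arrays left out. The 16 lists called became 0 with an estimated correlation and 0 with fry; elsewhere 13 to 16 were called, 15 with the replicate block, which changed no other call than the epicardial one. Same-numbered arrays did not deviate together (correlation 0.032), but 2 pairs cannot settle whether the numbers pair the samples. The epicardial list was also not called with a trend in camera, with the mean of all features, or without genes below 3.42 or 5.42, and the last 2 settings ended the smooth muscle call too. Of 357 list comparisons 314 kept direction and side of the threshold, 23 reversed, 18 weakened and 2 strengthened; of 1906 for named genes other than Smyd2 1788 kept both, 117 strengthened and 1 reversed, and Smyd2 reversed without Smyd2 replicate 2 (0.13). Reversed without genes below 5.42 were the medians for adrenergic signalling (0.0098), NRF2 (0.0022) and atrophy (0.014). Reversed with the mean of all features were Hbb-b1 (0.25; 5 of its 20 features had the sign of the feature used), p53 targets (−0.0658 in the list median, where camera's direction turned) and apoptosis (−0.031). With a trend, camera's direction turned for NRF2 (median −0.083). With arrays left out, list medians that reversed, or whose camera direction did, ranged as follows: cell cycle −0.25 to 0.18, NRF2 −0.097 to 0.0032, cholesterol −0.31 to 1.43, erythroid −0.61 to 0.077, adrenergic −0.26 to 0.060, unfolded protein response −0.097 to 0.046, p53 −0.24 to 0.063. Inflammatory genes ranged from −0.12 to 0.33, atrophy from −0.10 to 0.020, ribosomal proteins from −0.0001 to 0.0066, endothelial markers from 0.0092 to 0.30 and the SMYD family from −0.37 to 0.13. Medians that kept their sign ranged from 0.073 to 0.24 for TGF-beta targets, 0.044 to 0.23 for histone methyltransferases and 0.0019 to 0.13 for apoptosis regulators. Apart from fewer arrays or genes tested, the cause was not tested. Without detection flags the level of background was not measured, so dim values could not be told from it.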

Other observations

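The 5 lists of the next paragraph, and the tests of other cell types, of leukocytes, of 1 array alone and of the probe, were chosen after the data were seen; the matched lists and the splits were set before.

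Junction and phosphagen genes of cardiomyocytes were lower beside the sarcomere. Of 17 intercalated disc and desmosome genes 14 were lower and 3 higher, with a median of −0.83, and 8 fell adjusted over the list alone. The desmosomal cadherin Dsg2 read 9.05 ± 0.17 on the control arrays and 6.66 ± 0.22 on the arrays labelled Smyd2, and desmoplakin, Dsp, differed by −2.30 (SE 0.35). All 15 genes of a tricarboxylic acid cycle list were lower (median −0.78), with none past the test adjusted over the list alone. Of 20 mitochondrial ribosomal protein genes 19 were lower and 1 higher (median −0.46), again with none past that test. The cycle list also held Got1 and Got2, aspartate transaminases of the malate-aspartate shuttle, and Mdh1, its cytosolic malate dehydrogenase, which differed by −1.28 (SE 0.25), −0.70 (SE 0.23) and −0.97 (SE 0.25). Of 10 creatine and phosphagen genes 7 were lower and 3 higher (median −0.65). Adjusted over the list alone 3 fell, among them the muscle creatine kinases Ckm (−2.56, SE 0.41) and Ckmt2 (−2.21, SE 0.38), and 1 rose, Gamt, which makes creatine (1.14, SE 0.23). These 4 lists passed camera within a family of 35, with adjusted p of 4.16e-06, 3.11e-08, 5.61e-05 and 0.0368, against 0.557, 0.557, 0.557 and 0.646 with an estimated correlation. As the lists were chosen after the data were seen, these p-values describe them and add no independent support. Vascular growth factors and receptors did not pass (13 of 21 higher, 8 lower, median 0.26, camera adjusted p = 0.118 and 0.557 with an estimated correlation). That list was made after Angpt2 and Vegfd were seen among the 10 higher genes, so a test of them within it adds nothing; Angpt1, another member, differed by 1.89 (SE 0.38).

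The sarcomere list was lower on both arrays labelled Smyd2. Its median of −2.15 lay below the lowest median, −0.42, of 10000 lists matched on mean level, so other genes of that brightness did not share the fall. The deposited arrays have nearly the same distribution, which keeps matched lists near 0 (typical median −0.026). The comparison therefore cannot decide what normalization did to these genes. If the other cell types kept their proportions, a lower share of cardiomyocytes would raise the markers of all of them alike. Fibroblast markers exceeded endothelial ones by 0.75 in the median (20 and 12 markers with a mean of 6 or more, permutation p = 0.00454, two-sided over genes). That p treats genes as independent and does not measure the spread between cultures. Without beta-galactosidase replicate 1 the excess was only 0.17. A lower share with relatively more fibroblasts would also give an excess, so these markers cannot decide. A lower share therefore cannot be told apart from lower transcription within cardiomyocytes. The falls of the muscle genes Smyd1 (−2.36), Trim55 (−2.89) and Hspb3 (−2.48) were of similar size, and the same limit holds for them. The 16 sarcomere genes with a control mean of 6 to 15 had quartiles of −2.38 and −2.13, closer together than the median SE of 0.32. Their SD was 0.74, which came mostly from members outside the quartiles. It therefore cannot decide whether most of these genes fell by 1 shared factor. The whole list had quartiles of −2.22 and −1.42 with 2 members higher. It includes 3 members at the top of the scale on the control arrays only and 1 in both groups, whose differences are cut short or unreadable. An effect of the Smyd2 construct, which the design names, stays open as untested.

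The interferon list was higher on the arrays labelled Smyd2. One array alone does not carry it, since its lowest median with any array left out was 0.86, without Smyd2 replicate 1. A higher share of leukocytes may account for part of it. At a mean of 6 or more, 26 interferon genes had a median of 1.60 and 9 leukocyte markers 1.57. The difference was 0.036 (one-sided permutation p = 0.463 over genes, which treats them as independent). Over all 42 and 26 members the medians were 1.33 and 0.49, and without Smyd2 replicate 1 they were 0.86 and 0.15. Leukocytes therefore cannot be told apart from a response within the cardiomyocytes. A different viral dose between the constructs was not tested and also stays open.

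The Smyd2 feature was not higher where Smyd2 was to be expressed, at a difference of −0.12. A probe outside the expressed construct, or a construct of another species, may give this value, and the position of the probe, not analysed here, keeps this open beside weak expression and wrong labels.

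The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split, the 1 with the most genes, had 2363 genes at an unadjusted p under 0.05, and the highest other had 563. Every other split sets 1 array of each group on each side. Any difference between the groups then enters the spread and lowers the count, so 563 is not a level that chance would give.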
